A study of Mus musculus with 4 samples.

How the data were processed

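Mouse bone-marrow-derived macrophages were treated with lipid A, washed, and given lipid A again, and RNA of the cytosolic fraction was depleted of ribosomal RNA and made into 1 library from each of 4 biological replicates. The replicate numbers come from the labels, which call the 4 samples biological replicates and describe 1 condition, with no untreated control in the samples used here. The sex and age of the animals were not recorded in the labels. Each library had its own biosample record, and 1 donor record was named for all 4.

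For each library the submitters provided a gene table and 2 transcript tables. Per the file headers, the gene table and the first transcript table give expected counts, TPM, posterior mean TPM and a posterior standard deviation for each feature, and the second transcript table gives estimated counts and TPM. In the values, the deposited TPM of each library had a fixed total over all features, so they are relative values. The genome build was mm10 with the M21 annotation, per the deposited notes of each library, which also say that the first quantification was made from a transcriptome alignment and the second directly from the read files. All 55536 gene rows matched the GENCODE annotation of that release. The aligner, the quantification tools and their versions are not given in the sources used here. The gene table also held 26248 numbered rows of at most 259 bases, 96 ERCC spike-in rows, which had 0 counts in each library, and 1 phiX174 row.

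Expected counts summed to between 30660511 and 48223718 per library, and the second quantification's estimated counts to between 36212584 and 62013348. The deepest library therefore gives the finest resolution: 3 counts, the limit that a count of 0 allows, correspond to 0.0622 CPM (counts scaled to a fixed library total) in replicate 3 and 0.0978 in replicate 1. Exact binomial (Clopper-Pearson) intervals at 95% and these limits cover counting error only, since reads without molecular identifiers are not independent molecules.

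The tests, their samples, the gene lists and the rule for named genes were fixed before the data were examined. Genes with expected counts summing to at least 10 over the 4 libraries were tested with limma 3.58.1 (lmFit and eBayes with a variance trend, intercept only) on log2(TPM + 0.1), one-sided against the level of 1 TPM in each direction. Calls used a Benjamini-Hochberg adjusted p below 0.05, over all genes tested and over each list alone. There were 37 gene lists, with 607 distinct genes measured. Sting1, Atp5f1a, Norad and Oip5os1 were matched through synonyms, and Ahsp and Rigi were not matched and not used here. Where a symbol belonged to more than 1 gene, the gene with the higher mean TPM entered the list. A list's median was set among the medians of 10000 random lists of tested protein-coding genes of the same size. List contrasts were differences of the medians of tested members per library, tested with an exact sign-flip permutation and with 100000 permutations of list membership over genes, adjusted over 7 contrasts.

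The spread between replicates was the biological coefficient of variation of edgeR 4.0.16 (TMM, estimateDisp, intercept only) on expected counts rounded to whole numbers. List medians of the gene-wise values and of the deviation of each library from the other 3 (log2 CPM, genes with a mean count of at least 50) were set among 10000 random lists matched on expression in 20 bins. Class shares are shares of the expected counts on annotated genes. The quantifications were compared with limma treat (a log2 difference of 1, no variance trend) on the difference of log2(TPM + 0.1) within a library, for genes of at least 1 TPM on average in either. A first run of this comparison used a variance trend, which had not been planned, and it was taken out after its results had been seen. Transcript shares are percentages of a gene's TPM. DESeq2 1.42.0 served for alternative size factors and dispersions. The analyses ran in R 4.3.3 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), with figures drawn in matplotlib 3.10.9.

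The genes named are 24 genes fixed by name, the 15 with the highest mean TPM, the 3 members of each list with the highest mean TPM, the 10 with the largest and the 5 with the smallest spread among genes of at least 10 TPM, the 5 with the largest called difference in each direction between the quantifications among genes of at least 10 TPM in either, and 8 list members with the highest TPM in which the leading transcript holds under 60% of the gene's TPM in both quantifications. Other genes are named with a statement that they were chosen after their values were seen. Some genes that this rule selects are not reported here.

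The fits were tested on simulated data. Of 50 genes each simulated at 0.25, 0.5, 2 and 4 TPM among 15877 genes, 98% to 100% were called on the correct side, and 1 of 15049 calls lay on the wrong side. All genes were simulated with the same coefficient of 0.2, which was estimated as 0.201, and genes of very short effective length were left out. In the data the common value was 0.259, and genes near the level can vary more (Ifnb1 0.456, Il12b 0.504). Recovery at such a spread was not simulated. Simulated log2 differences of 2 and 3 in either direction between quantifications were called in 100% of 50 genes each, among 16186 genes. With no simulated difference, 2% of list contrasts had p below 0.05, and 98% did with a shift of 2 SD. That SD is the one of log2 mean TPM over 22345 genes, so recovery of smaller differences was not simulated. The simulated lists were drawn at random, so the 2% does not cover lists of genes regulated together. Alternatives covered the pseudocount, the filter, the quantification, the scaling, the variance model, the summary of a list, the normalization and dispersion tool, and leaving out each replicate in turn. Rescaling both quantifications to protein-coding genes was added after the data were seen. The simulation of random lists was enlarged after a smaller number of lists gave an uneven mean percentile, and the mean percentile was then 50.5. The numbered rows and spike-ins entered no test.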

Results

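The data were 4 libraries of ribosomal-RNA-depleted total RNA from the cytosolic fraction of bone-marrow-derived macrophages of C57BL/6J mice. Bone-marrow-derived macrophages are phagocytes grown in culture from marrow precursors. Lipid A is the part of bacterial lipopolysaccharide that Toll-like receptor 4 (TLR4) recognises. The cells had been pretreated with 100 ng/ml lipid A for 12 h, washed and kept without it for 12 h, and given 100 ng/ml lipid A again for 15 min. All 4 libraries belong to this 1 group and are labelled biological replicates 1 to 4. With 1 group, no value below is a response to lipid A, and no comparison between conditions was made. The questions put to the data were which genes lay above or below a fixed level beyond the spread of the replicates, how gene groups stood relative to one another, and how far the replicates differed. Expected counts summed to 30660511 in replicate 1, 36681241 in replicate 2, 48223718 in replicate 3 and 42785115 in replicate 4. The labels name 1 donor record for all 4 libraries and do not say whether cultures or animals were separate. The p-values of single genes and of sign-flip tests therefore measure only the spread between these samples, which may be technical. Those from permuting list membership measure the spread between genes. Values are TPM, the transcript abundance corrected for length and scaled to a fixed total per library, as mean ± SD over 4 libraries unless stated. Coordinates are on mm10.

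Of the 16262 genes tested, 9457 lay above 1 TPM, 5712 lay below it and 1093 had neither call (limma, Benjamini-Hochberg adjusted p below 0.05). Of those above, 8999 were protein-coding, out of 12636 protein-coding genes tested, and 202 were long noncoding. Most protein-coding genes tested thus lay above the level, and counts of list members below are to be read beside that share. Short noncoding RNAs took most of the TPM. Rn7s2 and Rn7s1, identical copies of the 7SL RNA of the signal recognition particle on chromosome 12 (69361182 to 69361481 and 69159295 to 69159594), stood at 300982 ± 23805 and 300500 ± 23945 TPM, and how the reads divide between the copies is uncertain. Rn7sk, the 7SK RNA that regulates transcription elongation, followed at 34864 ± 19883 TPM, with Rpph1, the RNA of RNase P, at 27969 ± 11384 TPM. Rmrp, the RNA of RNase MRP, is annotated as a ribozyme (8270 ± 5142 TPM) and as an overlapping lincRNA (3538 ± 942 TPM), between which reads are uncertain. The most abundant mRNAs were those of the ferritin chains Fth1 (19186 ± 2508 TPM) and Ftl1 (8189 ± 504 TPM), the chemokine Ccl5 (5322 ± 1570 TPM), thymosin Tmsb4x (5007 ± 1656 TPM), serum amyloid Saa3 (4377 ± 1518 TPM), Actb (4105 ± 1396 TPM), B2m (3652 ± 750 TPM), lysozyme Lyz2 (3430 ± 684 TPM) and the lysosomal Psap (3392 ± 840 TPM). TPM rescaled to protein-coding genes was higher by a factor of 3.17, 4.00, 3.37 and 2.74 in replicates 1 to 4, and 11031 genes then lay above the level and 3427 below it.

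By counts, which do not weight short RNAs up, nuclear-encoded protein-coding genes held 88.1% ± 2.43 (SD, n = 4) of the counts on annotated genes. 7SL RNA held 8.91% ± 1.70, and 7SK, RNase P and RNase MRP RNA together held 1.29% ± 0.623. Long noncoding genes held 0.904% ± 0.528, with 1.67% in replicate 2 (exact 95% interval 1.668 to 1.676) and 0.467% in replicate 1 (0.464 to 0.469). Pseudogenes held 0.415% ± 0.0386, but 8.65% by the counts of the second quantification. Ribosomal RNA held 0.115% ± 0.124 (0.263%, 0.0209%, 0.00463% and 0.170% in replicates 1 to 4, and 0.0652% without replicate 1), and snRNA, snoRNA and scaRNA 0.0184% ± 0.00898. Mitochondrially encoded mRNA held 0.262% ± 0.126, ribosomal protein mRNA 1.23% ± 0.121 and replication-dependent histone mRNA 0.0624% ± 0.00341. Sense intronic and still unconfirmed loci held 0.0563% ± 0.0365 and retained-intron transcripts 1.48% ± 0.368. By summed TPM the protein-coding share was 30.7% and the 7SL share 60.2%.

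The macrophage identity genes lay above the level without exception, 27 of 27, and 27 adjusted over the list alone. Their median was 340 ± 49.7 TPM, above each of 10000 random lists of tested protein-coding genes. The highest were Lyz2 and the lysosomal proteases Ctsd (2827 ± 405 TPM) and Ctsb (2133 ± 556 TPM). Markers of other cells were mostly low. No natural killer cell marker (0 of 8), erythroid marker (0 of 9), megakaryocyte marker (0 of 7), mast cell and basophil marker (0 of 8) or fibroblast and stroma marker (0 of 11) lay above the level. The negative control lists also gave 0 of 9 hepatocyte and 0 of 8 neuron genes. In each of these lists the count adjusted over the list alone was 0 as well. This adds little where 0 members (natural killer cell, hepatocyte) or 1 member (erythroid, mast cell and basophil, neuron) had enough counts for a test. Alb, Apoa1 and Ttr, secreted liver proteins, had 0 counts in each library, which allows up to 0.0871 TPM of Alb in replicate 1. Natural killer cell genes Nkg7 (0.0275 ± 0.0427 TPM), Gzma and Eomes (each 0.02 TPM in 1 library and 0 in the others), haemoglobin Hba-a1 (0.0350 ± 0.0473 TPM) and Alas2 (0.0725 ± 0.0629 TPM) had too few counts for a test. Epor (0.363 ± 0.242 TPM), Ppbp (0.243 ± 0.13 TPM), Itga2b (0.0850 ± 0.0520 TPM), Gp1ba (0.0650 ± 0.0238 TPM), Kit (0.190 ± 0.0779 TPM), Acta2 (0.160 ± 0.0392 TPM), Thy1 (0.0900 ± 0.0648 TPM), Sparc (0.0525 ± 0.0126 TPM) and Map2 (0.133 ± 0.153 TPM, and 0.0567 TPM without replicate 4) lay below it. Thy1 had too few counts for a test without replicate 1. Rescaled to protein-coding genes, Ppbp (0.790 TPM) and Kit (0.617 TPM) lost this call, as did Map2 with posterior mean TPM (0.825 TPM). By posterior mean TPM, Itga2b (0.728 TPM), Kit (0.530 TPM), Thy1 (0.355 TPM) and Sparc (0.235 TPM) also stood higher and were still called below. With the second quantification rescaled, Ppbp (0.774 TPM), Kit (0.779 TPM), Acta2 (0.777 TPM), Thy1 (1.12 TPM) and Map2 (0.482 TPM) lost it. Cpa3 (0.0400 ± 0.0424 TPM), Gata2 (0.0200 ± 0.0163 TPM) and Grin1 (0.01 TPM in 1 library and 0 in the others) had too few counts for a test, as did Snap25 at 0.

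A few markers of other cells passed. Among neutrophil and granulocyte precursor genes 3 of 12 lay above the level (3 adjusted over the list alone), namely the calgranulins S100a9 (6.25 ± 1.91 TPM) and S100a8 (4.54 ± 1.27 TPM) and the collagenase Mmp8 (2.28 ± 0.379 TPM). The T cell list gave 1 of 11 (1 adjusted over the list alone), the co-stimulatory receptor Cd28 at 23.2 ± 7.61 TPM, while Lck (0.0875 ± 0.0591 TPM) and Cd5 (0.0700 ± 0.0374 TPM) lay below. The B cell list gave 2 of 10 (2 adjusted over the list alone), the inhibitory receptor Cd22 at 6.99 ± 3.11 TPM and Cd79b at 1.36 ± 0.334 TPM, with Vpreb1 below at 0.11, 0.33, 0.09 and 0.11 TPM in replicates 1 to 4. Vpreb1 had too few counts for a test without replicate 2, and it lost its call when rescaled to protein-coding genes (0.569 TPM) and with the second quantification rescaled (0.745 TPM). The call of Cd79b was lost without replicate 1 (1.37 TPM), 3 (1.21 TPM) or 4 (1.37 TPM) and when no genes were filtered, and with the second quantification Cd79b lay below the level (0.463 TPM). Dendritic cell genes gave 1 of 8 (1 adjusted over the list alone), the transcription factor Batf3 at 2.06 ± 0.591 TPM, with Ccr7 uncalled (0.938 ± 0.422 TPM) and Clec9a below (0.110 ± 0.122 TPM, and 0.05 TPM without replicate 4). Osteoclast genes gave 2 of 8 (2 adjusted over the list alone), the tartrate-resistant phosphatase Acp5 at 13.2 ± 3.61 TPM and the proton pump subunit Atp6v0d2 at 5.42 ± 1.05 TPM, with the protease Ctsk uncalled (0.815 ± 0.333 TPM). Endothelial genes gave 2 of 8 (2 adjusted over the list alone), the VEGF receptor Kdr at 1.79, 3.36, 3.53 and 11.3 TPM in replicates 1 to 4 (mean without replicate 4 2.89 TPM) and Vwf at 3.01 ± 1.48 TPM, with Cdh5 below (0.595 ± 0.362 TPM). The call of Cdh5 was lost without replicate 2 (0.747 TPM) and with posterior mean TPM (0.708 TPM). By posterior mean TPM, Lck (0.415 TPM), Cd5 (0.115 TPM), Vpreb1 (0.375 TPM) and Clec9a (0.240 TPM) stood higher and were still called below. With the second quantification as deposited, Mmp8 (0.857 TPM), Vwf (0.875 TPM) and Kdr (1.61 TPM) had no call, and Batf3 (0.766 TPM), Ccr7 (0.321 TPM) and Ctsk (0.320 TPM) lay below the level. Ctsk also lay below it without replicate 4 (0.66 TPM) and when no genes were filtered. With TPM rescaled to protein-coding genes, Ccr7 and Ctsk passed as above it (3.00 and 2.59 TPM), and Epor and Cdh5 turned to the upper side without a call (1.23 and 1.84 TPM). With the second quantification rescaled, Ccr7 (2.82 TPM), Ctsk (2.89 TPM) and Cdh5 (2.59 TPM) lay above it.

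**Figure D1:**
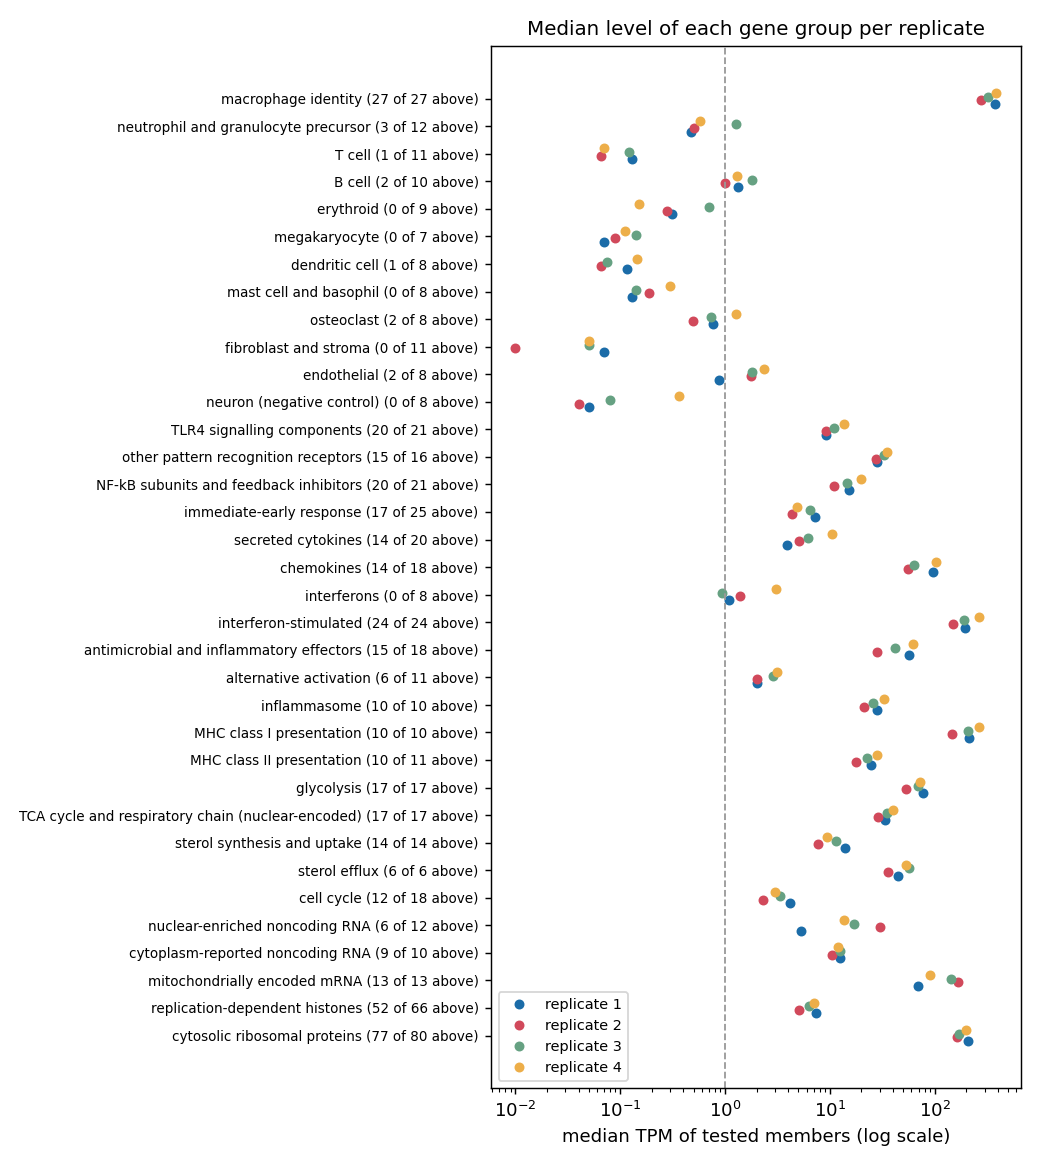
Median TPM of the tested members of each gene group, on a log axis, with 1 point per replicate the dashed line at 1 TPM and the members called above it out of those measured in the labels. The macrophage identity points lie near the mean of 340 TPM, while the fibroblast and stroma median was 0.0450 ± 0.0252 TPM.

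Of the TLR4 signalling components, 20 of 21 lay above the level (20 adjusted over the list alone). Their median was 10.7 ± 2.14 TPM, at the percentile 95.9 of the random lists. The co-receptor Cd14 stood at 67.0 ± 14 TPM, the adaptor Myd88 at 54.6 ± 13.2 TPM, the kinase adaptor Tab2 at 27.2 ± 4.62 TPM and Tlr4 itself at 25.7 ± 5.53 TPM. The exception was Lbp, the serum lipopolysaccharide carrier made in liver, at 0.550 ± 0.123 TPM, below the level. Among other pattern recognition receptors 15 of 16 lay above (15 adjusted over the list alone), median 30.8 ± 3.45 TPM. They were led by the C-type lectin Clec4e (112 ± 38.9 TPM), the RNA sensor Tlr7 (71.4 ± 19 TPM) and the lipopeptide receptor Tlr1 (65.6 ± 16.5 TPM). The flagellin receptor Tlr5 lay below at 0.0725 ± 0.0359 TPM. NF-kB subunits and feedback inhibitors gave 20 of 21 above the level (20 adjusted over the list alone), median 15.2 ± 3.75 TPM. Nfkbia, which encodes the inhibitor IkB-alpha, stood at 81.4 ± 27.1 TPM, the lipid phosphatase Inpp5d at 47.9 ± 7.59 TPM, the A20-binding protein Tnip3 at 45.3 ± 15.1 TPM, Tnfaip3, which encodes A20, at 24.1 ± 8.49 TPM and the inhibitory kinase homologue Irak3 at 16.9 ± 6.03 TPM. Sigirr lay below at 0.298 ± 0.149 TPM. Lbp, Tlr5 and Sigirr were named after their values were seen.

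Immediate-early genes, which are transcribed within minutes of a stimulus without new protein, were mixed. Of 25 measured, 17 lay above the level (17 adjusted over the list alone), 5 below and 2 had neither call, and their median was 5.72 ± 1.32 TPM, at the percentile 62.9 of the random lists. The highest were the repressor Atf3 (92.1 ± 33.9 TPM), Klf6 (83.6 ± 24.7 TPM) and Gadd45b (75.1 ± 41.6 TPM), followed by Junb (51.6 ± 8.20 TPM). Fos stood at 31.1, 11.3, 18.2 and 4.89 TPM in replicates 1 to 4, and Egr1 at 7.36, 2.16, 5.91 and 1.43 TPM. With the second quantification the call of Egr1 was lost (1.55 TPM).

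Secreted cytokines ranged from high to undetected. Of 20 measured, 14 lay above the level (14 adjusted over the list alone), 4 below and 1 had neither call, median 6.43 ± 2.92 TPM. Tgfb1 was highest (117 ± 15.6 TPM), then Ebi3, a subunit of interleukins 27 and 35 (87.2 ± 20.5 TPM), and Tnf (82.7 ± 35.2 TPM, chromosome 17, 35199381 to 35202007). Il1rn, which encodes the interleukin-1 receptor antagonist, stood at 57.0 ± 19.3 TPM, Il1b at 20.7 ± 9.57 TPM and the anti-inflammatory Il10 at 8.40 ± 2.79 TPM. Il12b lay just above at 2.18 ± 1.47 TPM, and its call was lost without replicate 1 (1.61 TPM), with TMM-scaled TPM (2.20 TPM) and with the second quantification (0.910 TPM). Il6 (chromosome 5, 30013114 to 30019981) had neither call, at 0.90, 0.80, 0.24 and 1.31 TPM in replicates 1 to 4. It passed as above the level once TPM was rescaled to protein-coding genes (2.61 TPM), and as below it with the second quantification as deposited (0.339 TPM).

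Chemokines were abundant, with 14 of 18 above the level (14 adjusted over the list alone) and a median of 79.2 ± 23.0 TPM. After Ccl5 (chromosome 11, 83525778 to 83530518), the highest were the interferon-inducible Cxcl10 (457 ± 302 TPM) and the monocyte attractant Ccl7 (246 ± 192 TPM, and 156 TPM without replicate 1). Interferon transcripts themselves were scarce. None of 8 lay above the level, and 1 did adjusted over the list alone, where it was the only member tested, so its p was in effect unadjusted. That gene was Ifnb1, at 1.09, 1.39, 0.94 and 3.06 TPM in replicates 1 to 4 (limma adjusted p = 0.0671 over all genes). Ifnb1 passed over all genes without replicate 1 (1.80 TPM) and without replicate 3 (1.85 TPM). It also passed with TPM rescaled to protein-coding genes (5.15 TPM), with the second quantification rescaled (6.11 TPM), with posterior means, with genes of at least 40 summed counts and when no genes were filtered, and stood under the level without a call with the second quantification (0.678 TPM). Ifng (0.0325 ± 0.0585 TPM) and Ifnk (0.0150 ± 0.0173 TPM) had too few counts for a test.

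Interferon-stimulated genes lay above the level in 24 of 24 cases (24 adjusted over the list alone), with a median of 199 ± 47.3 TPM, above each of the 10000 random lists. Ifit2 stood at 928 ± 326 TPM, the antiviral radical enzyme Rsad2 at 857 ± 400 TPM, the transcription factor Irf7 at 804 ± 256 TPM, the ubiquitin-like Isg15 at 716 ± 274 TPM (chromosome 4, 156199424 to 156200818) and Mx1 at 219 ± 89.7 TPM. Antimicrobial and inflammatory effectors gave 15 of 18 (15 adjusted over the list alone), median 47.2 ± 15.4 TPM. After Saa3 came Acod1, the itaconate-producing enzyme (377 ± 171 TPM, chromosome 14, 103046977 to 103056573), and the NADPH oxidase subunit Cybb (228 ± 48.7 TPM). Nos2, the inducible nitric oxide synthase, stood at 2.93, 2.54, 3.11 and 11.5 TPM in replicates 1 to 4, with a mean of 2.86 TPM without replicate 4, and its call was lost with the second quantification (1.65 TPM). Inflammasome genes gave 10 of 10 (10 adjusted over the list alone), median 26.9 ± 4.82 TPM, led by Casp1 (93.3 ± 23.2 TPM), the pore-forming Gsdmd (50.2 ± 13.2 TPM) and Casp4 (37.4 ± 14.2 TPM). Alternative activation genes were divided, with 6 of 11 above (6 adjusted over the list alone) and 4 below, median 2.5 ± 0.573 TPM. The scavenger receptor Stab1 (57.9 ± 5.07 TPM), Il4ra (43.3 ± 11.6 TPM) and the mannose receptor Mrc1 (21.5 ± 3.07 TPM) were above. Arg1 (0.0400 ± 0.0383 TPM) and Cd163 (0.0700 ± 0.0408 TPM), named after their values were seen, were below.

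Antigen presentation genes were expressed for both classes. MHC class I presentation gave 10 of 10 above the level (10 adjusted over the list alone), median 208 ± 48.3 TPM, with B2m, H2-K1 (2123 ± 455 TPM), H2-D1 (1637 ± 373 TPM) and the immunoproteasome subunit Psmb8 (220 ± 49.6 TPM). Reads of H2-K1 and H2-D1 can be shared between these paralogs, so their split is uncertain. MHC class II presentation gave 10 of 11 (10 adjusted over the list alone), median 23.2 ± 4.30 TPM, with Ctss (1330 ± 286 TPM), the invariant chain Cd74 (214 ± 45.7 TPM) and H2-Aa (61.1 ± 11.4 TPM).

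Metabolic genes lay above the level throughout. Glycolysis gave 17 of 17 (17 adjusted over the list alone), median 67.9 ± 10.6 TPM, with Gapdh (358 ± 32.6 TPM), Aldoa (184 ± 27.0 TPM) and Pkm (179 ± 31.8 TPM). The nuclear-encoded TCA cycle and respiratory chain list gave 17 of 17 (17 adjusted over the list alone), median 34.4 ± 4.57 TPM, with Cox4i1 (199 ± 18.1 TPM), Cox5a (179 ± 45.6 TPM) and Atp5a1 (98.9 ± 16.0 TPM). Sterol synthesis and uptake gave 14 of 14 (14 adjusted over the list alone), median 10.6 ± 2.72 TPM, with Hmgcs1 (26.6 ± 4.51 TPM) and Srebf2 (23.5 ± 3.27 TPM). Sterol efflux gave 6 of 6 (6 adjusted over the list alone), median 47.5 ± 9.04 TPM, with Apoe (1097 ± 410 TPM), Abcg1 (72.1 ± 22.2 TPM) and Abca1 (57.0 ± 15.6 TPM). Cell cycle genes were lower, with 12 of 18 above (12 adjusted over the list alone), 3 below and a median of 3.22 ± 0.781 TPM. That median stood at the percentile 25.4 of the random lists. With the second quantification as deposited, 4 cell cycle genes lay above. The DNA clamp Pcna (77.4 ± 21.6 TPM) and the replicative helicase subunits Mcm6 (15.2 ± 6.80 TPM) and Mcm3 (10.6 ± 4.98 TPM) were the highest.

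Among noncoding RNAs reported as nuclear, 6 of 12 lay above the level (6 adjusted over the list alone), median 16.4 ± 10.1 TPM. Malat1 (chromosome 19, 5795690 to 5802672), an abundant nuclear speckle RNA, stood at 55.7, 719, 416 and 295 TPM in replicates 1 to 4. Neat1, the scaffold of paraspeckles, stood at 9.62, 41.2, 31.7 and 21.1 TPM. Xist (chromosome X, 103460366 to 103483254), the X-inactivation RNA, stood at 0.61, 18.3, 2.39 and 6.12 TPM, and its call was lost without replicate 2 (3.04 TPM), without replicate 4 (7.09 TPM) and with the second quantification (2.30 TPM). Cytoplasm-reported noncoding RNAs gave 9 of 10 (9 adjusted over the list alone), median 11.8 ± 0.905 TPM, with 2900097C17Rik, the annotation's name for Norad (64.0 ± 7.07 TPM), Zfas1 (45.8 ± 15.5 TPM) and Gas5 (43.4 ± 5.76 TPM). Mitochondrially encoded mRNA gave 13 of 13 (13 adjusted over the list alone), median 117 ± 44.8 TPM, with mt-Atp8 (778 ± 311 TPM), mt-Co1 (609 ± 221 TPM) and mt-Nd6 (148 ± 60.6 TPM). Replication-dependent histones gave 52 of 66 (53 adjusted over the list alone), median 6.48 ± 1.04 TPM, with Hist2h2aa2 (124 ± 22.9 TPM), Hist1h2bc (61.1 ± 8.13 TPM) and Hist1h4m (41.0 ± 13.6 TPM). Histone genes are near-identical copies, so single values are uncertain. Cytosolic ribosomal proteins gave 77 of 80 (77 adjusted over the list alone), median 184 ± 21.4 TPM, with Rpl41 (805 ± 51.0 TPM), Rps24 (680 ± 93.8 TPM) and Rps29 (662 ± 105 TPM).

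**Figure D2:**
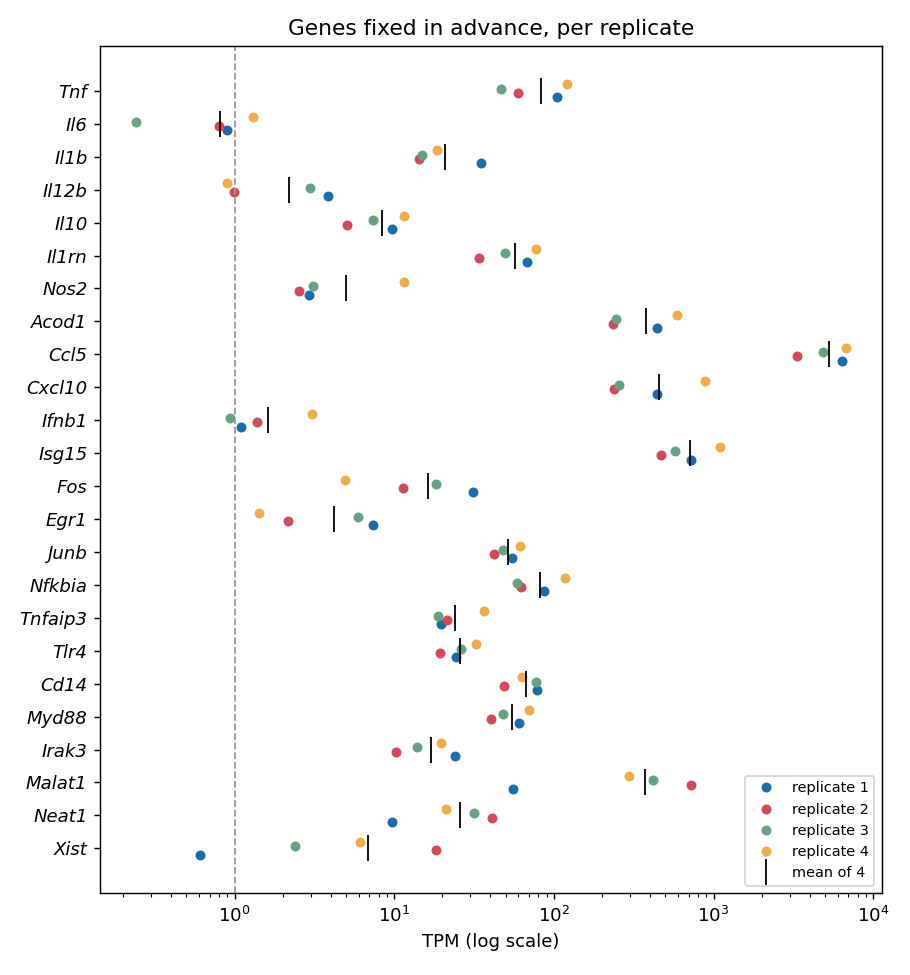
TPM of the 24 genes fixed in advance, on a log axis, with 1 point per replicate, a tick at the mean of 4 and the dashed line at 1 TPM. Ccl5 has the highest mean, 5322 TPM, and Il6 the lowest, 0.813 TPM, while Xist spans 0.61 to 18.3 TPM.

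Gene groups were then compared with one another inside each library, as the difference of the median log2(TPM + 0.1) of their tested members. An exact two-sided sign-flip permutation test over 4 libraries cannot go below p = 0.13, short of 0.05, so group membership was also permuted over genes, which are not independent replicates. Macrophage identity genes exceeded the 44 tested members of the other 13 cell type lists, of which the natural killer cell and hepatocyte lists had none, by 10.39 ± 0.16 (SD, n = 4) on the log2 scale, higher in 4 of 4 libraries (permutation p = 1e-05, the smallest that the permutations can give, Benjamini-Hochberg adjusted over 7 contrasts 3.5e-05). The size depended on the processing, from 8.20 with a pseudocount of 1 to 11.55 without a filter. Interferon-stimulated genes exceeded immediate-early genes by 5.09 ± 0.45, in 4 of 4 libraries (permutation adjusted p = 3.5e-05, raw 1e-05). MHC class I genes exceeded class II genes by 3.14 ± 0.09, in 4 of 4 libraries (permutation adjusted p = 0.00826, raw 0.00354). That call was lost with the second quantification as deposited (2.69, permutation adjusted p = 0.0769) and rescaled (2.70, permutation adjusted p = 0.0718, range over the alternatives 0.00604 to 0.0769). NF-kB subunits and feedback inhibitors exceeded secreted cytokines by 1.29 ± 0.46, in 4 of 4 libraries (permutation adjusted p = 0.0343, raw 0.0196). This call was lost without replicate 1 (1.07, permutation adjusted p = 0.0593) and with genes of at least 40 summed counts (0.23, permutation adjusted p = 0.847). It was also lost with posterior means, with means of log2 values, and with the second quantification as deposited and rescaled. Over the alternatives its adjusted p ranged from 0.00619 to 0.847.

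The remaining 3 contrasts did not pass. Chemokines stood 3.65 ± 0.63 above secreted cytokines in 4 of 4 libraries (permutation adjusted p = 0.103, raw 0.0735), and 2.59 above with genes of at least 40 summed counts. Glycolysis genes stood 0.97 ± 0.16 above the TCA cycle and respiratory chain in 4 of 4 libraries (permutation adjusted p = 0.226, raw 0.193), and 0.16 above with means of log2 values. Cytoplasm-reported noncoding RNAs stood 0.26 ± 1.36 above nuclear-enriched ones, in 3 of 4 libraries, with 1.91, -1.39, 0.48 and 0.05 in replicates 1 to 4 (permutation adjusted p = 0.860, raw 0.860), and the difference was -0.29 without replicate 1, -2.002 with means of log2 values and 2.16 without a filter. The sign-flip p was 0.13, the smallest possible, for each contrast except this last one, where it was 0.625 (exact).

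The common biological coefficient of variation from edgeR was 0.259 over 4 libraries, with a jackknife SE of 0.0732. By pairs it was highest between replicates 1 and 2 (0.420) and lowest between replicates 3 and 4 (0.175). Gene groups varied to different degrees. The nuclear-enriched noncoding RNAs had a median gene-wise value of 0.491 where lists matched on expression had 0.172. Chemokines had 0.362 against 0.164, cell cycle genes 0.337 against 0.196, mitochondrially encoded mRNA 0.331 against 0.152, and antimicrobial and inflammatory effectors 0.322 against 0.161, each of these 5 medians lying above every one of the 10000 matched lists. Cytosolic ribosomal proteins had 0.139 against 0.145 (percentile 2.25).

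In replicate 1 the cell cycle list stood 2.12-fold above the mean of the other 3 libraries (median of 16 genes, higher for 16 of 16), chemokines 1.47-fold above (12 of 15 genes higher), and nuclear-enriched noncoding RNAs at 0.267-fold (0 of 8 higher). In replicate 2 nuclear-enriched noncoding RNAs stood 3.95-fold above the others (8 of 8 higher) and mitochondrially encoded mRNA 1.98-fold above (13 of 13 higher), while antimicrobial and inflammatory effectors stood at 0.662-fold (0 of 15 higher). In replicate 3 mitochondrially encoded mRNA stood 1.41-fold above (11 of 13 higher) and chemokines at 0.665-fold (2 of 15 higher). In replicate 4 interferon-stimulated genes stood 1.45-fold above (24 of 24 higher), NF-kB subunits and feedback inhibitors above by 0.26 on the log2 scale (19 of 20 higher), and cell cycle genes at 0.658-fold (1 of 16 higher). Each of these medians lay outside all 10000 lists matched on expression, a description of single libraries and not a test between conditions. Medians of cytosolic ribosomal proteins also did so in each library, despite their small gene-wise spread. They stood at 1.15-fold, 1.06-fold, 0.907-fold and 0.918-fold in replicates 1 to 4, with 72, 71, 4 and 15 of 77 genes higher. Single genes at least 2-fold above the other 3 libraries numbered 214, 176, 29 and 77 in replicates 1 to 4, and those at least 2-fold below 225, 94, 40 and 56, of 10989 with a mean count of at least 50.

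**Figure D3:**
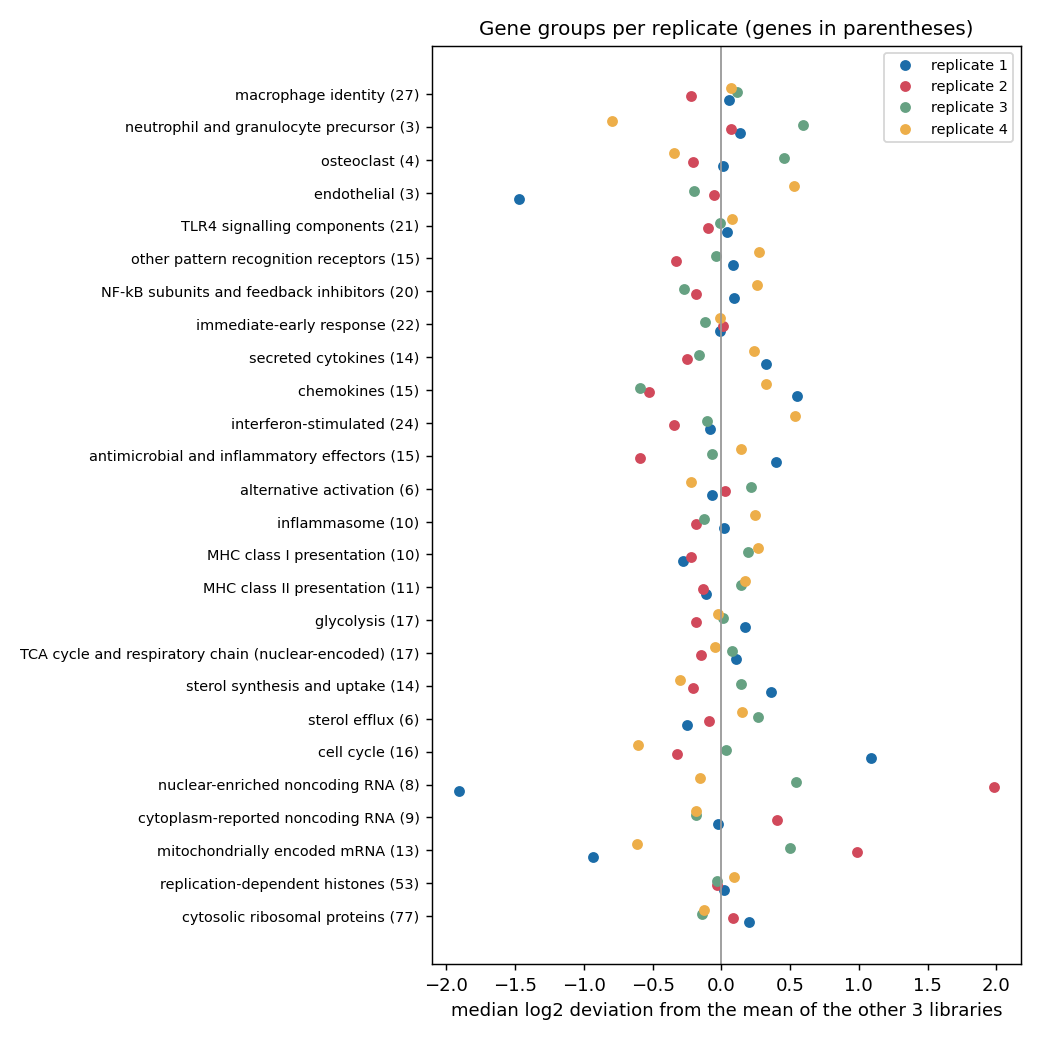
Median log2 deviation of each gene group in a replicate from the mean of the other 3 libraries, with 1 point per replicate and the number of genes in parentheses. Nuclear-enriched noncoding RNA spans -1.91 in replicate 1 to 1.98 in replicate 2, and cell cycle genes reach 1.09 in replicate 1.

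Single genes with the largest spread, among those of at least 10 TPM, were 9 short noncoding RNA genes and 1 pseudogene. The U3 snoRNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 were each listed at 0, 32.4, 0 and 21.5 TPM in replicates 1 to 4, and Rnu3a at 0, 29.5, 0 and 23.3 TPM. The snRNA genes Gm26244 (115, 0, 0.13 and 1.78 TPM), Gm24924 (115, 0, 0.13 and 155 TPM) and Gm24497 (0, 200, 6.56 and 152 TPM), the snoRNA gene Gm25835 (0, 88.8, 5.99 and 65.8 TPM) and the pseudogene Gm14303 (154, 2.35, 4.35 and 15.4 TPM, and 7.38 TPM without replicate 1) completed the 10. With posterior mean TPM, Gm26244 stood at 116 ± 28.3 TPM, Gm24924 at 131 ± 21.9 TPM and Gm24497 at 173 ± 87.1 TPM, and Gm26244, Gm24924, Gm25835 and the U3 genes, uncalled on TPM, lay above the level. They are uncertain where reads can move between similar copies. The call of Gm24497 was lost without replicate 2 or 4, with TMM-scaled TPM and with a pseudocount of 0.01. The smallest spreads were those of Brd7 (25.01 ± 3.62 TPM), Chtop (19.4 ± 2.52 TPM), Cln6 (19.4 ± 2.38 TPM), Idh3b (32.0 ± 3.51 TPM) and Flot2 (13.8 ± 1.84 TPM), with gene-wise coefficients of 0.112 each.

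Isoform use was repeatable between replicates. Genes with at least 2 annotated transcripts and at least 1 TPM in each library were compared, 8546 in all. For 94.6% ± 0.257 (SD, n = 4) of them, the most abundant transcript in the mean of 3 libraries was also the most abundant in the library left out. The leading transcript was protein-coding in 93.3% of these genes. H2-K1 divided between a transcript annotated as a retained intron (42.8% ± 5.01 of the gene's TPM) and a coding one (41.4% ± 3.06). In the second quantification these held 33.4% ± 8.19 and 50.6% ± 5.45. Psmb8 divided between a retained-intron transcript (48.6% ± 0.700) and a coding one (48.6% ± 0.972), which held 49.6% ± 0.923 and 47.6% ± 0.658 in the second. Mx1 was led by a transcript annotated for nonsense-mediated decay (53.4% ± 2.10), whose share was 33.2% ± 5.84 in the second. The leading transcript held 31.4% ± 1.68 of Rpl13a, 52.5% ± 5.41 of Rps27a and 51.7% ± 5.40 of Malat1, and in the second these transcripts held 14.1% ± 2.54, 43.7% ± 4.53 and 57.9% ± 11.6. There, a retained-intron transcript stood higher in Rpl13a (25.3% ± 3.30) and another coding transcript in Rps27a (55.9% ± 4.67). In the first quantification, that coding transcript also led Rps27a in replicates 1 (53.0% against 46.7%) and 4 (49.9% against 49.8%). The coding transcript led H2-K1 in replicate 4 (45.8% against 35.8%) and Psmb8 in replicates 1 and 3. The leaders of Mx1, Rpl13a and Malat1 stood above the transcript ranked next in each library.

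Each library also had a second transcript quantification. On TPM as deposited, the median gene differed by -1.40 on the log2 scale between the second and the first. With both rescaled to protein-coding genes, an alternative chosen after seeing the data, the median difference was 0.05, and of 14140 genes 471 were higher and 134 lower by more than 2-fold in the second (limma treat, adjusted). As deposited, and so with that shift left in, 229 of 10329 genes were higher and 442 lower. The lower count was 278 without replicate 3, 276 without replicate 4, and 5711 with a variance trend, which was taken out after its results had been seen. As deposited, the 5 genes highest in the second were the processed pseudogenes Gm12896 (chromosome 4, 122122847 to 122123072) and Gm12895 (chromosome 4, 122455210 to 122455435), at 159941 ± 96861 and 159908 ± 96805 TPM, and the miRNA-annotated genes Gm24245, Gm24270 and Gm23935, at the same 120441 ± 63129 TPM each. All 5 had 0 counts in the first quantification. The 5 lowest in the second were Gm10222 (122 ± 52.7 TPM in the first), Gm26716 (131 ± 20.3 TPM), Gm10076 (325 ± 53.0 TPM), Gm10443 (50.3 ± 9.57 TPM) and Gm15899 (38.4 ± 21.3 TPM), all at or under 0.505 TPM in the second. By annotation these 5 are 3 pseudogenes, an antisense gene and a lincRNA, and their values are uncertain where reads are shared with similar or overlapping genes. The leading transcript was the same in both quantifications for 90.6% of the 8546 genes of the isoform comparison.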

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

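Neither weighing nor further testing was done for the values in this part, which were picked by a rule fixed before they were seen. In each set of 4 replicates, a value was taken to stand apart when its gap to the nearest other value exceeded 0.83 of the whole range. Of 222 sets checked, 20 had such a value. For independent, normally distributed values the rule marks about 1 in 20 sets, or 11.1. The sets checked were not of that kind, since all came from the same 4 libraries. Gzma, Eomes and Grin1 had a detectable TPM in 1 library only, which sets that value apart by construction. Map2 entered both as a gene and as the neuron list's median. The 20 sets therefore cannot be read as an excess over chance.

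Replicate 1 stood apart with 4.59 on the log2 scale for chemokines against secreted cytokines (median of the others 3.33), 115.16 TPM of Gm26244 (0.13), 153.62 TPM of Gm14303 (4.35), 0.12 TPM of Ifng (0), 0.02 TPM of Eomes (0) and 0.01 TPM of Grin1 (0). Replicate 2 stood apart with the lowest share of counts on nuclear-encoded protein-coding genes, 84.472% (89.5%), with 36.61 TPM of Inpp5d (51.7), 155.52 TPM of Cybb (253), 7.83 TPM of Acp5 (14.5) and 0.33 TPM of Vpreb1 (0.11). Replicate 3 stood apart with a median of 1.28 TPM over the neutrophil and granulocyte precursor list (0.51) and 0.02 TPM of Gzma (0). Replicate 4 stood apart with 11.52 TPM of Nos2 (2.93), 36.74 TPM of Tnfaip3 (19.6), 99.57 TPM of Tlr7 (60.5), 120.26 TPM of Klf6 (69.8) and 58.45 TPM of Casp4 (29.6). It also did with 0.36 TPM of Map2 (0.05), the single tested gene behind the neuron list's median of 0.36 TPM. All TPM in this part were as deposited, and the factor to the protein-coding scale was highest in replicate 2 (4.00) and lowest in replicate 4 (2.74). The deposited scale thus lowers values of replicate 2 and raises those of replicate 4. The rule was not applied on the protein-coding scale.

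Reads of phiX174, a bacteriophage genome used as a sequencing control, entered no comparison. They numbered 117349 in replicate 1, 113212 in replicate 2, 76923 in replicate 3 and 10187 in replicate 4, above the 3 counts that a count of 0 allows.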

How the results depend on the processing

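The second quantification with both tables rescaled to protein-coding genes, and the comparison of quantifications on that scale or with a variance trend, were chosen after seeing the data, and the other alternatives were planned. Counts of genes above 1 TPM stayed within 1.5 times under each alternative (7336 to 11057). No paired analysis was possible because there is only 1 group. The cause was not tested for any change below, unless fewer or more genes tested gave it. As deposited, the median gene differed by -1.40 on the log2 scale between the second quantification and the first. Calls that changed with the second quantification as deposited can follow from this shift. Without a filter, limma warned that most residual variances were 0, so those calls are unreliable. Depth limits genes near 1 count.

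Genes below 1 TPM numbered 45184 without a filter, 2800 with counts summing to 40, 3427 rescaled to protein-coding genes and 2659 with the second quantification rescaled. Members above the level became 1 for B cell without a filter and with the second quantification, and 1 for interferons without a filter, with counts summing to 40, with posterior means and on both rescaled scales. The second quantification as deposited gave 0 for dendritic cell, 0 for endothelial and 4 for cell cycle, and both rescaled scales gave 2 for dendritic cell. Leaving out a replicate gave 1 to 2 for B cell and 0 to 1 for interferons.

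NF-kB against cytokines was 0.23 with counts summing to 40, 1.27 with posterior means, 1.21 with the second quantification, 1.24 with it rescaled and 1.59 with means of log2 values, all without a call, and 1.05 to 1.32 without a replicate. Macrophage identity against other cell types was 8.20 with pseudocount 1, 9.10 with counts summing to 40, 9.25 with posterior means and 11.55 without a filter. Glycolysis against the TCA cycle was 0.16 with means of log2 values. MHC class I against II was 2.69 with the second quantification and 2.70 with it rescaled, without a call. Cytoplasmic against nuclear noncoding RNA was -2.002 with means of log2 values, 2.16 without a filter and -0.29 to 0.81 without a replicate.

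As shares of summed TPM, protein-coding genes held 30.7%, 7SL RNA 60.2%, 7SK with RNase P and MRP RNA 7.47%, long noncoding 0.365%, small nuclear and nucleolar 0.585%, ribosomal protein 1.64%, histone 0.0817% and retained-intron 0.996%. By the second quantification's counts, protein-coding genes held 78.6%, pseudogenes 8.65%, sense intronic 0.136%, ribosomal protein 1.01% and histone 0.0562%.

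Higher and lower genes in the second quantification numbered 97 and 1321 with pseudocount 1, 31 and 3113 at 10 TPM, 130 and 198 without a filter, 471 and 134 with both rescaled, and 229 and 5711 with a variance trend, with 276 to 492 lower without a replicate. Isoform repeatability was 95.9% at 10 TPM and 94.1% to 94.5% without a replicate.

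On the protein-coding scale and with the second quantification on it, the other side of the level was taken by Il6 (2.61 and 2.91 TPM), Ccr7 (3.00 and 2.82), Ctsk (2.59 and 2.89), Epor (1.23 and 1.19) and Cdh5 (1.84 and 2.59). With the second quantification as deposited, this held for Il12b (0.910), Ifnb1 (0.678), Mmp8 (0.857), Cd79b (0.463), Batf3 (0.766), Vwf (0.875) and Gm10076 (0.505). With both rescaled, the log2 difference between the quantifications was 0.16 for Il12b, 0.27 for Ifnb1, 0.041 for Mmp8 and -0.070 for Cd79b. It was 0.085 for Batf3 and -0.28 for Vwf. For these genes, Gm10076 aside, most of the change thus went with the shift in scale. As deposited and rescaled, Gm26244 stood at 0.0194 and 0.146, Gm24924 at 0.0335 and 0.276 and Gm26716 at 0.0663 and 0.507, and Gm14303, Gm10222, Gm10443, Gm15899 and the U3 genes were listed at 0. With pseudocount 0.01 the fitted log level of Gm26244 (29.27 TPM), Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 (13.46) and Rnu3a (13.20) turned below. With posterior means Gm26244 stood at 116 and Gm24924 at 131. Without a replicate, Ccr7 ranged from 0.777 to 1.12, the Rnu3b genes from 7.16 to 17.94 and Rnu3a from 7.77 to 17.6.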

Other observations

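Of the tests in this part, those on retained introns and genomic DNA were stated before their results were seen, and the others only after. Of the annotated genes, 528 had a mean of at least 100 TPM and 10088 a mean of at least 1 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each of the 4 libraries, while Xist held 325 expected counts in replicate 1, 19386 in replicate 2, 2786 in replicate 3 and 5006 in replicate 4.

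Nuclear-retained RNA differed between replicates, with Malat1 highest in replicate 2 and lowest in replicate 1. TPM scaling by short RNAs was argued against, since Malat1 stayed 16.3 times higher in replicate 2 than in replicate 1 on the protein-coding scale. The scaling factors, 4.00 and 3.17, were too close to give such a difference. For genomic DNA, 1135 olfactory receptor genes gained -9.21e-05% of the gain of Malat1. A gain like that of Malat1 over so many genes would exceed the whole library, so this test could not have favoured genomic DNA. No conclusion on genomic DNA is drawn from it. Reads of these genes, scaled by length and depth, were 0.0264 in replicate 1 and 0.0252 in replicate 2, without a rise. Varying carry-over of nuclear RNA into the cytosolic fraction stays open and may contribute, since retained-intron transcripts took a share of counts 1.76 times larger in replicate 2 than in replicate 1, but a smaller one in replicate 3 (1.33%) than in replicate 4 (1.46%), while Malat1 stood at 416 TPM in replicate 3 and 295 TPM in replicate 4. For 7SK, RNase P and RNase MRP RNA carry-over cannot be told apart from other sources, since the composition of the nuclear RNA was not measured: on the protein-coding scale they were 1.54 times higher in replicate 3 than in replicate 2 (range over 3 genes 1.33 to 1.61, with 1.32 for both Rmrp entries summed). No biological explanation was tested, because the design has 1 group.

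Mitochondrially encoded mRNA also differed, highest in replicate 2 and lowest in replicate 1, and no biological explanation was tested. A joint rise of respiratory gene expression in replicate 2 was argued against. The nuclear-encoded respiratory list deviated there by -0.15 on the log2 scale, where 0.49 was needed, with a spread of 0.14 over genes. Of its 17 genes, 3 were higher than in the other libraries. That deviation is larger in size than the bound of 0.1 set for the absence of an effect, but has the opposite direction. Neither outcome stated for this test was therefore met, and it did not cover the other replicates. The same carry-over as for nuclear RNA cannot be told apart from other sources: summed mitochondrial TPM ranked the replicates as Malat1 did in 4 of 4 cases, but the highest and lowest were known beforehand, which left 2 possible orders. On the protein-coding scale replicate 4 stood 1.14 times above replicate 1 for mitochondrial mRNA and 4.59 times for Malat1.

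In the second quantification, Gm12895, Gm12896, Gm24245, Gm24270 and Gm23935 took 68.1% ± 7.44 (SD, n = 4) of the TPM and had 0 counts in the first. Their effective lengths were 15.2 to 68.1 bases, which raises their share of TPM above their share of counts. Short effective length does not by itself give them counts, and these 5 genes also held 10.6% ± 4.57 of the estimated counts. The limits of this test were set with its values known, so no verdict on length is drawn from it. Tool differences beyond 2-fold in most genes were argued against. After rescaling to protein-coding genes, 4.28% of the genes compared were called beyond 2-fold, and the median size was 0.11 on the log2 scale. The median gene cannot speak for these 5 genes, so tool differences cannot be told apart from other sources for them. Small differences between the tools in other genes stay open. Reads that the aligned quantification did not count may be a source, since the second quantification's excess of total counts was 1.31 to 2.10 times the counts of these genes. Where those reads come from was not tested, and no biological explanation was tested.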
